A study of Homo sapiens with 10 samples.

How the data were processed

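RNA 5-methylcytosine (m5C) was measured by methylated RNA immunoprecipitation and sequencing (MeRIP-seq) in MDA-468 and MCF-10A cells. Per the labels' protocols, polyadenylated RNA was chemically fragmented to about 100 nt, 25 µg of it was incubated with 7 µg of an antibody against 5-methylcytosine, and part of the fragmented RNA was kept as input. Per the labels' protocols, libraries were made with an Illumina TruSeq kit without a further polyA step and read as 50 bp single reads on a HiSeq instrument. The 10 samples fell into 5 groups of 2 by their titles: MeRIP and input of each line, and a technical replicate of the MCF-10A MeRIP. MCF-10A thus had more MeRIP libraries than MDA-468. The labels give the same culture description, which names MDA-MB-468, for every sample, and nothing says whether the replicates came from separate cultures.

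The 3 deposited files were a list of m5C sites for each line and a table of sites that differ between the lines. TopHat and hg19 are named in the submitters' processing notes, and Tophat2, exomePeak and UCSC known genes in the title lines of the differential table, per the file headers. The rule by which a site counted as consistent between replicates, the way replicates were pooled, and whether the technical replicates entered the MCF-10A list are not given in the sources used here. Each site in the lists carried a p-value deposited by the authors, which stands at 0 where it was too small for the number format. The differential table held a fold enrichment of MeRIP over input, a ratio computed by the authors. It also held the authors' log2 fold change between the lines. The remaining columns were logarithms of p-values and false discovery rates on a score scale, deposited by the authors, whose lowest differential value was -434, and 337 cells of the false discovery rate of site calling held a spreadsheet error in place of a value.

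The title line of the differential table and its name gave opposite directions for the comparison, so the direction was settled from the site lists. Of the 389 sites with a positive log2 fold change in the authors' deposited table, 381 overlapped a site of the MDA-468 list and 19 a site of the MCF-10A list, so positive values were read as higher in MDA-468. No file held values per library, so neither the spread between replicates nor the sequencing depth was known, and the 2 lines were compared as 2 lists. Tests between lists compare these lists, not the conditions, and genes and sites are not replicates. Both site p-values and the number of sites called depend on depth.

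Sites were compared with bedtools 2.31.1. A site counted as shared when its exon blocks overlapped a site of the other list by at least 1 bp on the same strand. Shares of sites carry exact Clopper-Pearson 95% intervals, which cover the counting of sites only. Coordinates are those of the files, in hg19, counted from 1. Genes were taken from the Entrez identifiers in the files and named through a RefSeq gene table. Names were found for 3677 of 3704 identifiers in the MCF-10A list, for 5249 of 5280 in the MDA-468 list and for 1523 of 1535 in the differential table. No hg19 annotation was used here, so the place of a site within a transcript (coding or untranslated) was not analysed here.

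Gene lists were fixed before the data were examined. A list was tested with a two-sided Fisher's exact test of genes with a site in MCF-10A only against genes with a site in MDA-468 only, members against all other such genes, where at least 5 members had a site in exactly 1 line. Fisher's exact tests were also made for each chromosome, with the sites on it against all others. Both families were adjusted by Benjamini-Hochberg at a threshold of 0.05. Medians were compared by two-sided permutation tests with 100000 resamples, with 95% bootstrap intervals from 2000 resamples. The calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for plots.

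The procedures were tested on simulated data first. In 50 simulations on the 2960 named genes with a site in exactly 1 line, lists of 40 genes with a share shifted toward MCF-10A were called in 100% of cases and unshifted lists of 14 genes in 1.11%, for the list test. The lists tested here were smaller, with 5 to 20 such genes. In 200 further simulations per size, 1 list with 30% of its genes in MDA-468 only, against 76.6% of all, was called in 16.5% of cases at 5 genes, 50.5% at 8, 72% at 13 and 97% at 20. A list that did not pass is therefore not shown to lack a difference, and a list of 13 genes all in MDA-468 only would have p = 0.0477 by Fisher's exact test before adjustment. The permutation test gave p-values under 0.05 in 6% of 100 null comparisons. The overlap procedure found 100% of sites moved by a distance shorter than the site, a result that was near certain beforehand. It also found 1.68% of sites that had been dropped.

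The genes named were set by a rule written beforehand. It takes the 12 genes with the largest absolute log2 fold change in the authors' deposited table, the 8 genes with most sites in each line among genes with no site in the other, the 6 genes with most sites over both lists, up to 4 members with most sites of each gene list, and every member of the lists of m5C proteins and of genes known to be altered in 1 of the lines. It took 138 genes, some of which are not reported here. Other genes are named as members of small counts and were chosen after their values were seen. Sex-linked genes of chromosome Y and the X-inactivation transcripts were counted but never named. Alternatives covered the threshold, the definition of overlap, the list length, the counting of sites or genes and, added after the data were seen, gene lists counted in the differential table. For the closing observations, the GC content, the length and a 14-nt core of the Alu repeat (either orientation) were taken from the longest protein-coding GENCODE transcript of each gene, for 19132 genes, without using coordinates.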

Results

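The series compared m5C in polyadenylated RNA of MDA-468, a human breast cancer line, with that of MCF-10A, a non-tumorigenic human mammary epithelial line. MeRIP and input libraries were made in 2 replicates for each line, with 2 further technical replicates of the MCF-10A MeRIP. The deposited files hold a merged site list for each line and a table of differential sites, so the sequencing depth is unknown and no value has a replicate error.

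The first comparison was of the sites called in each line. The MDA-468 list held 8320 sites in 5280 genes, and the MCF-10A list held 5194 sites in 3704 genes. Sites were longer in MCF-10A, with a median of 270 nt against 180 nt, a difference of 90 nt (95% bootstrap interval 90 to 91; permutation test, p = 1e-05, the smallest these permutations can give). The sites covered 1456 kb of exons in MCF-10A and 1644 kb in MDA-468. Most genes had a single site, 77.1% of those in the MCF-10A list and 70.7% of those in the MDA-468 list. The median p-value of the authors was 2.5e-53 in the MCF-10A list and 4e-13 in the MDA-468 list, and these p-values are used only within a list. The largest was 3e-08 in the MCF-10A list and 2e-05 in the MDA-468 list, so the lists did not end at the same p-value. A limit of 1e-05 left 5194 and 8303 sites and did not make the lists equal in this respect. How far this adds to the number of sites in MDA-468 only was not tested.

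HIVEP3, a large zinc finger transcription factor gene, had 12 sites in MDA-468 and none in MCF-10A, between positions 41972216 and 42050130 of chromosome 1. The mucin genes MUC12 (8 sites), MUC4 (7) and MUC5B (7), the eye and brain regulator PAX6 (7), RREB1 (7), TCHH (6), which encodes the hair follicle protein trichohyalin, and ARHGEF7 (6) also had sites in MDA-468 only. Neither HIVEP3 nor any of these genes had a differential site in the authors' deposited table. Among genes with sites in MCF-10A only, CLEC19A had 3 sites. XAF1, LINC01122, ZDHHC20, ZNF667, WWTR1-AS1 and the ion cotransporter gene SLC12A2 had 2 sites each in MCF-10A only. Of these and CLEC19A, only XAF1, ZNF667 and SLC12A2 had a differential site in the authors' deposited table. Over both lines, the most sites lay in the pseudogenes ANKRD20A9P (13 in MCF-10A and 12 in MDA-468) and LOC100131257 (14 and 9), followed by CYP20A1 (9 and 11), the translesion polymerase gene POLH (8 and 8), TOR1AIP2 (9 and 7) and ORAI2 (7 and 8). Reads of ANKRD20A9P and LOC100131257 can be shared with related copies, so their sites are uncertain. The placement of reads in repeats was not tested for the other genes named here either.

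The lines shared most MCF-10A sites and fewer of the MDA-468 sites. Of the 5194 MCF-10A sites, 3857 (74.3%, 95% interval 73.0 to 75.4) overlapped an MDA-468 site, and of the 8320 MDA-468 sites, 3965 (47.7%, 46.6 to 48.7) overlapped an MCF-10A site. When the MDA-468 list was reduced to the length of the other by best p-value, the shares were 62.4% and 63.2%. In total, 3004 genes had a site in both lines, 700 in MCF-10A only and 2276 in MDA-468 only. A site in 1 list only is not a tested difference between the lines. The authors' deposited table held sites higher in MDA-468 in 322 genes and sites higher in MCF-10A in 1226. Among 20056 protein-coding genes, 2464 had a site in both lines, against 681 if the gene sets were independent, a ratio of 3.62. Genes without RNA in these cells count in that background, since transcript levels were not analysed here. The 14-nt Alu core stood in the transcript of 61.6% of protein-coding genes with a site in both lines, of 27.6% with a site in MCF-10A only and of 4.06% with a site in MDA-468 only.

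Shared sites were called with smaller p-values than sites of 1 line. In MCF-10A, the median of -log10 p was 76.9 at 3857 shared sites and 18.5 at 1337 others, a difference of 58.4 (95% bootstrap interval 55.8 to 61.1; permutation test, p = 1e-05, the smallest possible). In MDA-468, the medians were 18.3 at 3965 shared sites and 9.59 at 4355 others, a difference of 8.72 (8.25 to 9.33; permutation test, p = 1e-05, the smallest possible).

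Of 14 m5C enzymes and binding proteins, 4 had a site. NSUN4, a mitochondrial rRNA methyltransferase gene, had 2 sites in MCF-10A and 4 in MDA-468, and the tRNA methyltransferase gene TRDMT1 had 1 in each line, at 17187079 to 17187349 and 17187139 to 17187289 of chromosome 10. NSUN6 had 1 site in MCF-10A only and TET3 had 1 in MDA-468 only. NSUN2, NOP2, NSUN3, NSUN5, NSUN7, ALYREF, YBX1, TET1, TET2 and ALKBH1 had no site in either list. Of 18 m6A proteins, 6 had a site, 1 in both lines (FTO), 1 in MCF-10A only and 4 in MDA-468 only, with 4 sites in ZC3H13. Of the 8 genes known to be altered in 1 of the lines, EGFR, which is amplified in MDA-468, had 2 sites in MDA-468 only, at 55238010 to 55238577 and 55270432 to 55270761 of chromosome 7. EGFR had no differential site in the authors' deposited table. SMAD4, which is reported as homozygously deleted in MDA-468, had 1 site in each list, at 48606893 to 48607252 of chromosome 18 in MCF-10A (the authors' peak p-value 1e-51) and within that stretch, at 48607042 to 48607222, in MDA-468 (5e-14). RB1, CDKN2A, CDKN2B and MYC had no site.

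Of 35 luminal and simple epithelial markers, 4 had a site in MCF-10A only, among them CDH1, which encodes E-cadherin, and the epithelial transcription factor genes ELF3 and GRHL2. GATA3, with 3 sites, was the single luminal marker with sites in MDA-468 only, and ERBB3 had sites in both. The odds ratio was 13.1, which did not pass adjustment over the 14 lists tested (two-sided Fisher's exact test, p = 0.0122, adjusted p = 0.118). Of 33 basal and mesenchymal markers, 4 had a site in both lines (AXL, CAV2, CD109 and MET), 2 in MCF-10A only (ZEB1 and ZEB2) and 5 in MDA-468 only, among them COL17A1, KRT14, MMP14 and TP63. Of 43 matrix and integrin genes, 3 had a site in both lines, 1 in MCF-10A only and 11 in MDA-468 only, with 3 sites in COL17A1 and 2 in ITGB4. Of 39 actin and junction genes, 3 had a site in both, 1 in MCF-10A only and 5 in MDA-468 only, with 1 site in MCF-10A and 4 in MDA-468 for the motor gene MYO10. Markers of cells that the cultures should lack also had sites: 6 of 18 fibroblast and stromal markers, such as PECAM1 (2 sites in each line), and 6 of 20 blood cell markers, such as CD68 and LYZ (1 in each line).

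Chromatin regulators had the largest share of members with a site, 31 of 60 (51.7%), of which 11 had a site in both lines, 1 in MCF-10A only and 19 in MDA-468 only. Members included the acetyltransferase gene CREBBP (1 site in MCF-10A and 4 in MDA-468), BRD3 (1 and 3), the methyltransferase gene NSD2 (2 and 3) and the deacetylase gene HDAC2 (3 and 2). The odds ratio of 0.171 did not pass the threshold (two-sided Fisher's exact test, p = 0.0609, adjusted p = 0.284). Splicing factors had a site in both lines in 4 of 52 members, in MCF-10A only in 7, such as HNRNPL and U2AF1, and in MDA-468 only in 6, such as SON and RBM25, an odds ratio of 3.84 that did not pass adjustment (two-sided Fisher's exact test, p = 0.0169, adjusted p = 0.118). Of 36 breast cancer drivers, 5 had a site in both lines, 3 in MCF-10A only and 6 in MDA-468 only, and the ubiquitin ligase gene MDM2 had 3 sites in MCF-10A and 2 in MDA-468. Of 51 genes of EGFR, RAS and PI3K signalling, 10 had a site in both lines, 1 in MCF-10A only and 7 in MDA-468 only. None of the 14 lists tested passed adjustment by Fisher's exact test, and 2 had an unadjusted p under 0.05. These lists held 5 to 20 genes with a site in exactly 1 line, and a list of 20 such genes all in MDA-468 only would have p = 0.00689 by Fisher's exact test, or an adjusted p of 0.0965 over 14 lists if the others had p = 1. When all genes with a site formed the background, luminal markers (odds ratio 15.2) and splicing factors (5.34) passed (Fisher's exact test, adjusted p = 0.0239 for both). With the MDA-468 list thinned to equal length, their odds ratios were 4.20 and 1.47 (Fisher's exact test, adjusted p = 0.872 for both), and with sites counted in place of genes 2.33 and 1.24 (Fisher's exact test, adjusted p = 0.979 and 0.982).

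Among genes of basic metabolism and protein synthesis, a site stood in 12 of 79 cytosolic ribosomal protein genes, 8 of them in both lines, with 3 sites in each line for RPL15. It stood in 13 of 53 translation factor genes, 8 in both lines and 5 in MDA-468 only. Of 68 oxidative phosphorylation genes 9 had a site, of 40 proteasome genes 5, of 27 glycolysis genes 2 (GPI and PFKFB3) and of 23 aminoacyl-tRNA synthetase genes 3 (SARS1, HARS1 and LARS1). Of 30 genes of cholesterol and fatty acid synthesis, 7 had a site, 6 of them in both lines, such as ACACA and CYP51A1. Of 59 cell cycle genes 18 had a site and 11 had it in both lines, such as CDK4 and RRM2, and of 38 DNA repair genes 11 had a site, with 2 sites in each line for ATM. Of 37 chaperone genes 9 had a site, 6 of them in MDA-468 only, such as HSP90AA1 and CANX. Of 46 interferon and antigen presentation genes 8 had a site, 6 of them in both lines, such as IRF1 and TAPBP. Of 26 long noncoding and vault RNAs 6 had a site, with 3 sites in MDA-468 only for H19. None of the 19 replication-dependent histone genes of the list had a site. The assay used polyadenylated RNA, and whether it held transcripts of these genes was not analysed here, so their lack of sites does not show a lack of m5C.

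**Figure D1:**
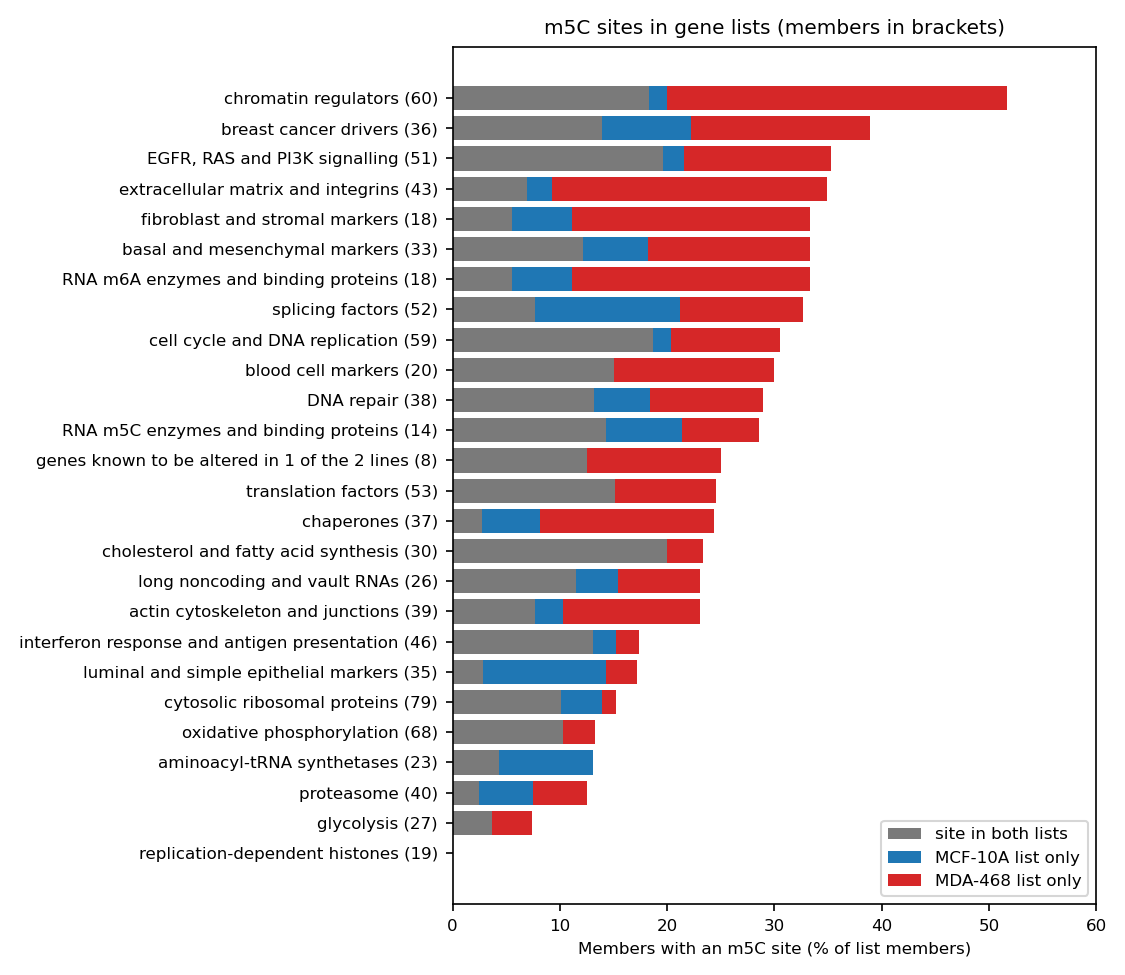
Percent of the members of each gene list with an m5C site, stacked by whether the site was in both lists (grey), in the MCF-10A list only (blue) or in the MDA-468 list only (red), with the number of members in brackets. Chromatin regulators stand highest at 51.7%, against 25.3% of all protein-coding genes and a mean of 40.1% in random lists matched on transcript length. None of the 19 replication-dependent histone genes had a site, and their presence in the polyadenylated RNA was not analysed here.

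The second comparison was the authors' own test of differences between the lines. In the authors' deposited table, 1795 sites differed, 1406 (78.3%) of them higher in MCF-10A and 389 (21.7%) higher in MDA-468. Sites higher in MCF-10A had a median log2 fold change of -1.96 (interquartile range -2.31 to -1.70) in the authors' deposited table, and those higher in MDA-468 a median of 3.09 (2.21 to 4.16). Their median fold enrichment of MeRIP over input in the authors' deposited table was 23 for sites higher in MCF-10A and 4.32 for those higher in MDA-468. Of the sites higher in MCF-10A in the authors' deposited table, 86.8% lay in both site lists, against 4.88% of those higher in MDA-468. These shares were not tested, since the same overlaps with the site lists had served to settle the direction of the comparison. The table lists only sites that passed the authors' threshold.

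The largest log2 fold change in the authors' deposited table was -10.5, in RARRES1, a retinoid-responsive gene, at 158414956 to 158415135 of chromosome 3. Next among sites higher in MCF-10A in the authors' deposited table were SLC2A10 (-7.70), ANKRD20A9P (-7.33), TET1 (-7.11), ANO1 (-6.97), the calprotectin subunit gene S100A8 (-6.85) and HOXC10 (-6.44). Higher in MDA-468 in the authors' deposited table were the homeobox gene IRX1 (8.13, at 3599969 to 3600239 of chromosome 5), DENND3 (7.78), PRDM8 (7.08), ZNF575 (6.61) and CMTM1 (6.55). Sites in RARRES1, TET1, ANO1 and S100A8 from the authors' deposited table overlapped neither site list. The epithelial genes ELF3 (-5.91 and -4.61) and ERBB3 (-4.17 and -3.09) had 2 sites each that were higher in MCF-10A in the authors' deposited table. Sites of IFIT3 (-2.96), TAPBP (-1.16) and IRF1 (-1.65), all of interferon response or antigen presentation, were also higher in MCF-10A in the authors' deposited table. In 13 genes, MYO10 among them (-2.23 and 2.54), the authors' deposited table listed sites in both directions.

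**Figure D2:**
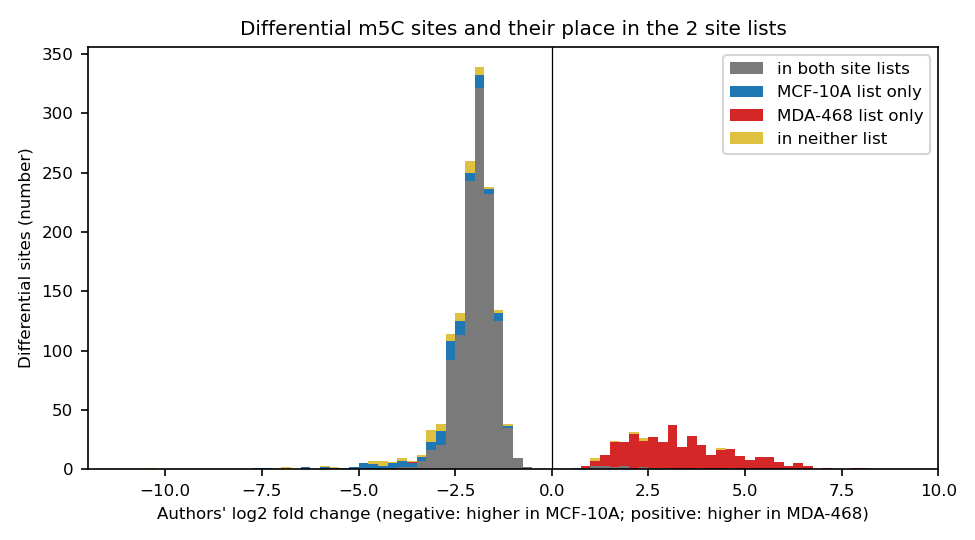
Number of differential sites by the authors' log2 fold change, coloured by whether a site overlaps both site lists (grey), the MCF-10A list only (blue), the MDA-468 list only (red) or neither (yellow). The 1406 sites higher in MCF-10A gather near their median of -1.96 and mostly lie in both lists, while the 389 sites higher in MDA-468 spread around a median of 3.09.

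Chromatin regulators leaned to MDA-468 in the authors' deposited table, with 7 genes higher in MDA-468 (among them CREBBP, KDM6B, KMT2A, KMT2D, NCOR1 and SETD1A) and 2 higher in MCF-10A (DNMT3A and HDAC2). Other genes of the authors' deposited table counted 300 and 1201 (two-sided Fisher's exact test, odds ratio for MCF-10A 0.0714, adjusted p = 0.00267 over 8 lists). Chaperones, with 4 genes higher in MDA-468 (CALR, CANX, HSP90AA1 and HSP90AB1) and 1 in MCF-10A in the authors' deposited table, also passed (odds ratio 0.0630, Fisher's exact test, adjusted p = 0.0220). So did splicing factors and breast cancer drivers, each with 5 genes higher in MDA-468 and 3 in MCF-10A in the authors' deposited table (odds ratio 0.151, Fisher's exact test, adjusted p = 0.0220). Among the chaperones, fold enrichment over input in the authors' deposited table was 1.16 at the CANX site and 1.79 at the HSP90AA1 site. It was 10.8 at the site of DNAJC3, the chaperone higher in MCF-10A. This ratio may not be that of MDA-468 alone. The authors' peak p-value for CANX was 1e-184 in the MDA-468 list and 1.5e-07 in their deposited table. For HSP90AA1 these peak p-values were 1e-119 and 1e-162. KMT2D and NCOR1 count among both drivers and chromatin regulators, and the odds ratio of splicing factors in the site lists, 3.84, lay on the other side of 1 without passing. All 7 ribosomal protein genes and all 5 interferon genes of the authors' deposited table had sites higher in MCF-10A, which did not pass (Fisher's exact test, adjusted p = 0.475 and 0.636). This count was chosen after the data were seen, and transcripts of genes higher in MDA-468 in the authors' deposited table had a median GC content of 54.0%, against 45.8% for those higher in MCF-10A. The Alu core stood in 9.89% of the former and 66.1% of the latter. It stood in 5% of chromatin regulators, 2.70% of chaperones, 9.62% of splicing factors and 16.7% of breast cancer drivers. Whether GC content or the Alu core accounts for these counts was not tested.

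The mitochondrial genome carried 17 sites in MCF-10A, over 9.10 kb counted for each strand by itself, and 5 in MDA-468, over 1.62 kb. Some MCF-10A sites lay opposite each other on the strands. The sites at 7587 to 7823 (plus) and 7587 to 7855 (minus) had the same p-value of the authors for the peak, 1e-292. The same reads may therefore count on both strands, which was not tested. All 11 mitochondrial sites of the authors' deposited table were higher in MCF-10A, with log2 fold changes from -4.55 to -1.01. The lowest value in the authors' deposited table lay at 236 to 368, on the minus strand, and the highest at 10471 to 12138.

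Sites were spread over the nuclear chromosomes in unlike shares in the lines. Chromosome 11 held 6.11% of the MDA-468 sites and 3.81% of the MCF-10A sites (two-sided Fisher's exact test, odds ratio for MCF-10A 0.609, adjusted p = 8.18e-08). Of the 23 chromosomes tested by Fisher's exact test, 8 passed, and chromosomes 6, 11, 13 and 17 held larger shares in MDA-468 while 2, 3, 12 and 15 did so in MCF-10A. With genes in place of sites, only chromosome 11 passed Fisher's exact test (odds ratio 0.709, adjusted p = 0.0101).

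**Figure D3:**
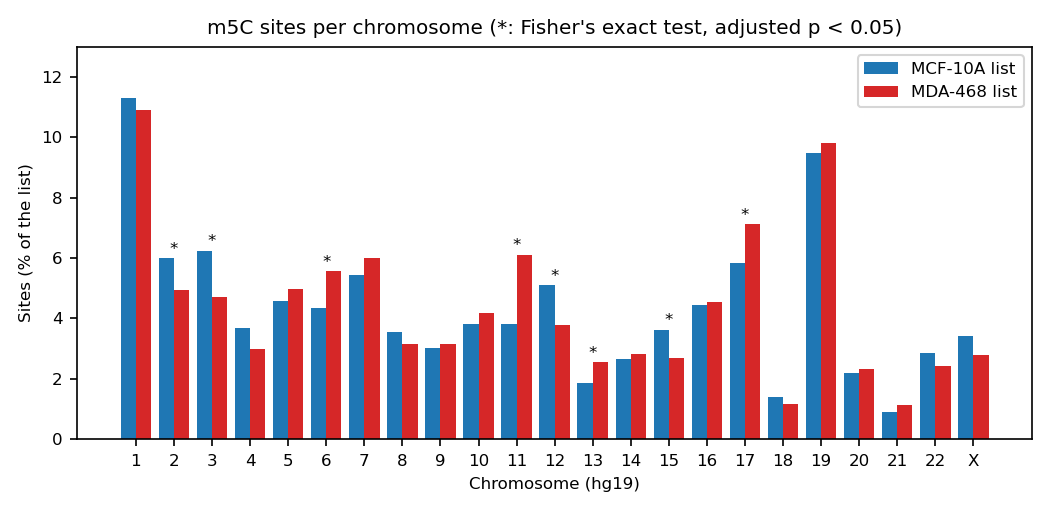
Percent of the sites of each list on each nuclear chromosome except Y, for MCF-10A (blue) and MDA-468 (red), with a star where Fisher's exact test passed after adjustment. Chromosome 11 shows the widest relative gap among those with a star, 3.81% against 6.11%.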

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

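The share of sites on 8 chromosomes differed between the lines by Fisher's exact test of the 2 lists. The odds ratios for MCF-10A were 1.22 on chromosome 2, 1.34 on chromosome 3, 1.37 on chromosome 12 and 1.35 on chromosome 15. They were 0.768 on chromosome 6, 0.609 on chromosome 11, 0.728 on chromosome 13 and 0.807 on chromosome 17. Only chromosome 11 passed in the main setting and in all 3 alternatives (genes with a site, merged sites, and the better 50% of each list). No explanation for these shares was tested, since neither transcript levels nor DNA copy number were analysed here.

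Sites without a gene identifier entered no gene comparison and numbered 164 (3.16%) in the MCF-10A list and 524 (6.30%) in the MDA-468 list. The difference between these shares was not tested.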

How the results depend on the processing

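Of the alternative values of main results, 41 stayed within 1.5 times the count, the interval or the side of the threshold, and 28 moved. For the odds ratios of single lists and chromosomes, 13 alternatives stayed on the same side of the threshold, 15 no longer passed, 2 newly passed and 1 reversed. No paired analysis was possible because no file holds values per library, so leaving out replicates and a replicate block were not run, and the place of sites in transcripts was not run for want of an hg19 annotation used here. Depth is not given, so how far it limits site calling is unknown.

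With the better 50% of each list by p-value, 2597 and 4160 sites remained by construction. The overlap of MCF-10A and MDA-468 sites was then 90.4% and 57.5%, genes in both, MCF-10A only and MDA-468 only were 1946, 161 and 1173, and 1 chromosome passed. Reciprocal 50% overlap gave 64.0% and 38.6%, and a window of 500 bp gave 77.8% and 49.4%. Thinning MDA-468 by best p-value gave 62.4% and 63.2%, with 1094 and 1140 genes in 1 line, and random thinning gave 47.6% of MCF-10A sites and 1562 genes in MCF-10A only. With genes counted in a line only from 2 sites on, 639 counted in both, 210 in MCF-10A only and 909 in MDA-468 only, and a gene with 1 site in the other line counts here as a 1-line gene. Fewer sites or a stricter overlap follow from how these alternatives are built.

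In the authors' deposited table, a false discovery rate of 1e-05 left 424 and 113 sites higher in MCF-10A and MDA-468, and an absolute log2 fold change of 2 left 663 and 317. Reciprocal 50% overlap left 5 of the 19 sites higher in MDA-468 that overlapped the MCF-10A list. With all genes with a site as background 2 gene lists passed, against 0 in the main test. With genes of differential sites, an alternative chosen after the data were seen, 4 passed and the odds ratio of splicing factors turned from 3.84 to 0.151; the cause was not tested. With genes in place of sites, 1 chromosome passed against 8.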

Other observations

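The gene families, sequence features and length matching in this part were chosen after the site lists had been seen. In total 5 patterns were looked at and 3 are weighed, and of their tests, those of shared reads and of developmental transcription factors were set after their results were known. Developmental transcription factor genes, taken by name (HOX, PAX, SOX, FOX, NKX and similar), had a site in MDA-468 only in 75 of 235 members and in MCF-10A only in 6 (odds ratio 3.65, 95% interval 1.51 to 7.60; two-sided Fisher's exact test, p = 0.000567, adjusted p = 0.00106 over 9 family tests). Those in MDA-468 only included HOXA9, PAX9, NKX2-1, LHX2 and GATA4, and those in MCF-10A only were HOXB4, HOXC8, HOXC10, POU2F3, SOX2 and TBX1. In the authors' deposited table, 10 such genes were higher in MDA-468 and 4 in MCF-10A (Fisher's exact test, adjusted p = 0.000246). ZNF genes, which encode zinc finger proteins, went the other way, with 24 of 509 in MDA-468 only, 31 in MCF-10A only and 132 in both (odds ratio for MDA-468 0.211, Fisher's exact test, adjusted p = 2.33e-07). In the authors' deposited table, 6 ZNF genes were higher in MDA-468 and 53 in MCF-10A, which did not pass (odds ratio 0.399, Fisher's exact test, adjusted p = 0.0507). Of 392 olfactory receptor genes, 3 had a site in both lines, 1 in MCF-10A only and 3 in MDA-468 only.

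A combination of 6 lists of abundant housekeeping mRNAs (ribosomal proteins, oxidative phosphorylation, proteasome, glycolysis, translation factors and chaperones) had a site in 16.5% of 303 genes, which stood at the 5.78th percentile of 10000 random lists matched on transcript length (mean 19.8%). Markers of other cell types had one in 31.6% of 38 genes, at the 83.8th percentile of their own matched lists (mean 24.9%). Of 25 single lists compared in this way, without adjustment for their number, glycolysis stood at the 0.7th percentile and actin and junction genes at the 3.26th. Blood cell markers stood at the 94.6th and chromatin regulators at the 96.8th (matched mean 40.1%), and the others lay between the 5th and the 95th. Among the others, the 19 replication-dependent histone genes, none with a site, stood at the 13.2th percentile (matched mean 6.61%). The MDA-468 site in SMAD4, a gene reported as deleted in that line, lay within the MCF-10A site, and neither the identity of the libraries nor the placement of its reads was tested.

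Alu repeats went with sites shared between the lines. The Alu core stood in 61.6% of genes with a site in both lines and in 7.06% of genes with none (odds ratio 21.1), and in 66.1% of genes higher in MCF-10A in the authors' deposited table against 9.89% of those higher in MDA-468 (Fisher's exact test, p = 5.56e-69). The tables argue against transcript length as the whole cause, since the pooled odds ratio over 5 length strata was 13.7 (12.3 to 15.3). Reads shared between repeat copies stay open: 86.3% of genes with an Alu core and a site had it in both lines, against 28.6% without a core, but 63.8% of all genes with a core had any site and the files hold no mapping quality. m5C in Alu elements may be a biological reading of this pattern, which cannot be told apart from shared reads here, and neither the position of the core relative to the site nor transcript levels were tested.

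Transcripts of genes with a site in MDA-468 only were richer in GC, with a median of 56.7% against 46.9% for MCF-10A only (permutation test, p = 1e-05, the smallest possible). The length of the MDA-468 list does not account for this, since the difference was 9.67 percentage points (8.76 to 10.7) with equal lengths. Alu repeats marked by the exact core do not either, since the difference was 9.83 points (8.83 to 11.0) among genes without a core in their longest transcript. Alu copies without the exact core, or in other transcripts of a gene, were not looked for. A GC bias between the libraries is a candidate explanation, which predicts the same lean within genes with a site in both lists. There, 48 genes with sites higher in MDA-468 exceeded 917 higher in MCF-10A by 8.77 points (3.59 to 11.5). A difference between the lines in which transcripts carry m5C, or are made, can give the same lean. The check therefore cannot tell these explanations apart, and both stay open. It was not repeated among genes without an Alu core.

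The lean of developmental transcription factors to MDA-468 may follow from GC content, as their median was 57.0%. Pooled over 5 GC strata the odds ratio was 2.54 (1.08 to 5.96), lower than without strata and with an interval that ends just above 1. Only 6 members had a site in MCF-10A only, and the family was chosen after the lists had been seen. GC content can also still differ within a stratum, so GC content is not excluded as the cause. With the MDA-468 list thinned to equal length the odds ratio was 2.99 (1.53 to 5.51), which argues against list length. Expression of these genes in the lines, and DNA in the RNA samples, were not tested and stay open.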
